A study of Mus musculus with 6 samples.

How the data were processed

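Kidney RNA from 6 samples of unilaterally nephrectomised mice, 3 given vehicle and 3 given 0.1% D-serine in drinking water, was extracted with TRIzol and made into libraries with a TruSeq stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes, the tools were TopHat2 2.0.13 and Bowtie2 2.2.3, which align reads, SAMtools 0.1.19, and Cufflinks 2.2.1, which estimates transcript levels, with the genome build mm10. The authors deposited 1 table of FPKM values per sample, and the same 24346 gene symbols stood in each. FPKM divides fragments by transcript length and by the total of mapped fragments, so that a few abundant genes press on all others. Kap, an androgen-regulated gene of the proximal tubule, held 11.6 to 15.9% of the FPKM sum of a library. The gene annotation, the read length and the strand setting are not given in the sources used here. Cufflinks can fail to estimate a gene and list it at 0: Rpl26, a ribosomal protein gene that cells need, was listed at 0 in all 6 libraries. An exact 0 is therefore reported only as listed at 0.

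Depth was estimated from the values, because the deposited FPKM tables hold no counts. Low genes differ between libraries by whole steps that reflect depth. The relative depth was 1, 0.954 and 0.902 for vehicle replicates 1 to 3 and 0.893, 0.836 and 0.882 for D-serine replicates 1 to 3. From 180 genes with 1 annotated transcript, the totals came to 8640000, 8240000, 7790000, 7710000, 7220000 and 7620000 mapped fragments in the same order, which is a rough estimate that depends on the transcript models. Low genes carry the most counting error at this depth, and no interval was computed from estimated totals.

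The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), between the 2 groups of 3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, with no minimum fold. Genes with a mean of at least 1 FPKM over the 6 libraries were tested, 11737 in all. The pseudocount of 1 FPKM understates the change of low genes, and every log2 difference is on that scale. An exact permutation test of 3 against 3 cannot give a two-sided p below 0.1, so none was used for single genes. Gene lists were tested with camera from limma with a preset correlation of 0.01 between genes, over the 33 pathway lists with at least 5 tested members, and the marker lists of cell types formed their own family with 12 of 22 lists tested. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction, were run beside it. The median, the mean and the test of each called list had the same sign.

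The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 called genes with the largest rise and the 10 with the largest fall whose libraries did not overlap, leaving out predicted and small RNA genes, and filled each side to 10 by the smallest unadjusted p. It added the 4 members with the smallest p from each called pathway list and from 5 lists of special interest, called or not, and 14 genes named in any case: Hk2, Pfkp, Pkm, Ldha, Slc2a1, Mtor, Rps6kb1, Ddit4, Dao, Srr, Mki67, Ccnd1, Cdkn1a and Grin1. Not each of these genes is reported here. Other genes are named as members of marker lists or for their position.

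The scripts were tested on simulated data. With 200 of 11737 genes changed in the comparison of D-serine with vehicle, limma recovered 80% at 2-fold with 5 false calls, 96% at 4-fold with 6 false calls, and 0% at 1.5-fold. A list shifted by 0.5 log2 was called by camera with either correlation and by fry, and with no change 0 genes and 0 lists were called. The simulated genes varied independently, unlike real ones, so the list results do not carry over to lists of correlated genes.

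Positions, transcript lengths and GC content came from GENCODE release M21, on the mm10 assembly, matched by symbol for 11309 of the tested genes (96.4%). The alternatives were another pseudocount (0.1 or 0.01), another minimum (none, or 5 FPKM), other scalings (median of ratios, quantile, or a fixed sum), limma without the trend, weighted libraries, the replicate number as a block, leaving out small RNA genes, and leaving out each library in turn. Removing a loess trend on the length and GC content of the longest annotated transcript (span 0.5) from each library was added after seeing the data. A count test was not run, because FPKM are not counts.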

Results

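Kidney messenger RNA was profiled by RNA-seq in 6 samples from mice that had undergone unilateral nephrectomy, the surgical removal of 1 kidney, after which the kidney that remains enlarges. Before the operation the mice received a serine-free diet for 1 week with drinking water that held either no addition (vehicle, 3 samples) or 0.1% D-serine (3 samples), and tissue was taken 2 days after the operation. D-serine is the mirror-image form of the amino acid L-serine. It binds a site of the NMDA-type glutamate receptor and is broken down in the kidney by D-amino acid oxidase. Sham-operated mice were not analysed here. The values are FPKM, the number of sequenced fragments of a gene divided by its transcript length and by the library total, for 24346 genes. The files hold no read totals. The spacing of the lowest values gave a rough estimate of 7220000 to 8640000 mapped fragments per library, so that 1 FPKM of a 2 kb transcript stood for about 15.7 fragments in an average library. D-serine replicate 2 was the shallowest library, at 0.836 of the depth of vehicle replicate 1. The labels do not say whether each sample came from its own mouse, so p-values measure the spread between these samples.

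The comparison asked which kidney transcripts differ with D-serine during remodelling after nephrectomy. The series title names glycolysis and the mTOR pathway, and both were tested as gene lists fixed before the data were examined. Genes of cell division were higher in the D-serine kidneys, the messenger RNA of Mtor itself was lower, and the glycolysis list did not pass its test. Markers of the proximal tubule and genes that respond to androgens were lower, and markers of the collecting duct were higher. Among 33 pathway lists, 16 passed camera, a test of a list against all other genes, with 8 higher and 8 lower. This call assumed a preset correlation of 0.01 between genes, and with an estimated correlation 0 of the 33 lists passed (lowest adjusted p = 0.48). The estimate ran from -0.068 for phosphate, calcium and vitamin D handling to 0.81 for G2/M and mitosis. For the latter the preset was far too low by this estimate.

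Cell division genes showed the largest list difference. In the list of G2/M and mitosis genes, 37 of 38 tested members were higher with D-serine, with a median log2 difference of 1.65, or 3.14-fold (camera adjusted p = 6.1e-19, and adjusted p = 0.48 with an estimated correlation). Adjusted over the list alone, 36 members rose, and over all genes tested 0 passed in limma. Of the 38, 36 had D-serine libraries that did not overlap the vehicle libraries, where chance gives 10% for 3 against 3 and 35.8% of all tested genes did not overlap (1932 higher, 2274 lower). Cenpa, the centromeric histone H3 variant, was at 1.21 ± 0.145 FPKM with vehicle and 12.1 ± 7.44 FPKM with D-serine (SD, n = 3 each). Ube2c, which marks mitotic cyclins for destruction, was at 3.72 ± 0.857 and 33.7 ± 23.0 FPKM. Birc5, the chromosomal passenger protein survivin, was at 4.99 ± 0.669 and 41.9 ± 30.3 FPKM. Kif23, a kinesin of cytokinesis, was at 1.78 ± 0.362 and 6.33 ± 2.18 FPKM, and the proliferation marker Mki67 at 1.05 ± 0.163 and 7.30 ± 5.38 FPKM. These 5 genes passed over the list alone and not over all genes (adjusted p from 0.057 to 0.067 in limma). The wide SD with D-serine came from replicate 1, which held the highest value of each of the 5 genes, such as 76.8 FPKM of Birc5 against 26.4 and 22.5 FPKM in the other D-serine libraries. Without it, the list's median was 1.17.

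**Figure D1:**
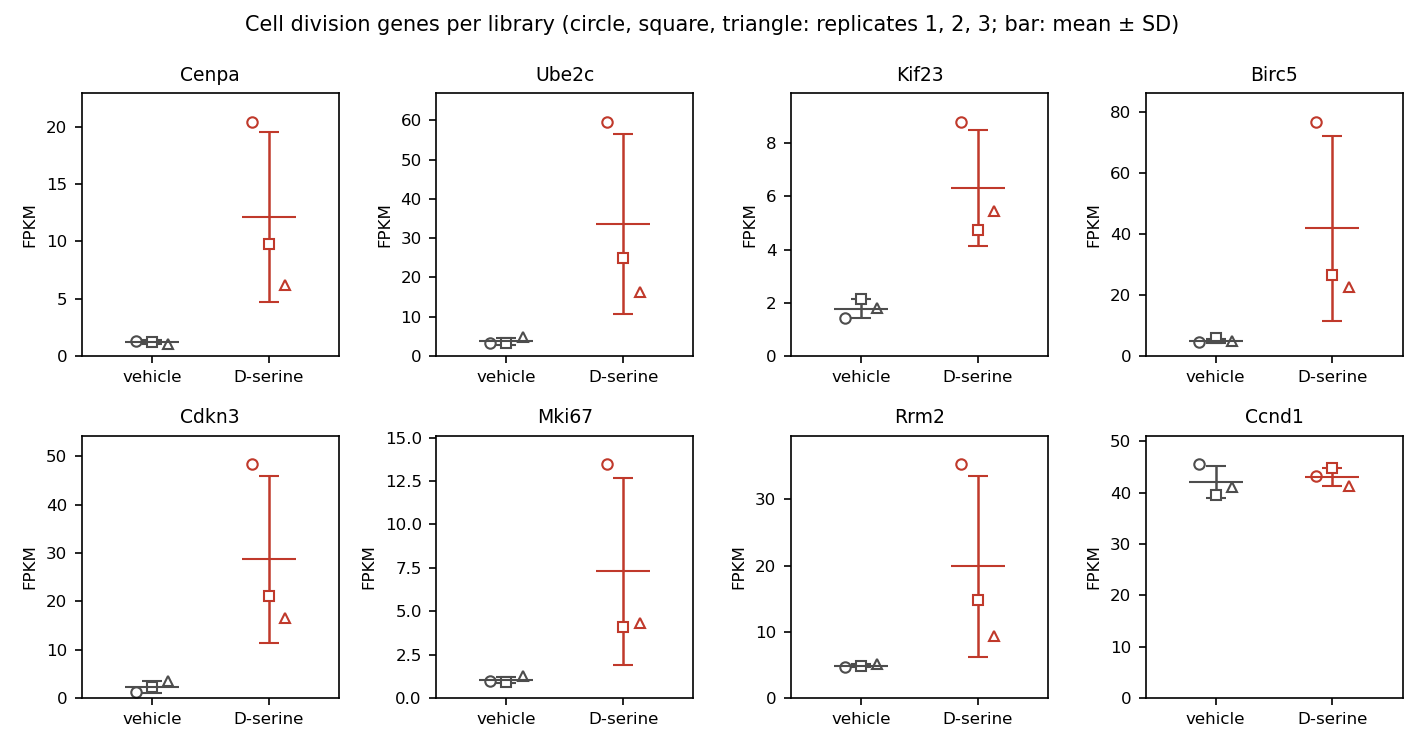
FPKM of 8 cell division genes (vertical axes, each from 0) in the vehicle and D-serine libraries, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 libraries. D-serine replicate 1 holds the highest value of each gene except Ccnd1, whose groups overlap.

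The G1/S and DNA replication list passed as well, with 30 of 32 tested members higher and a median log2 difference of 0.39 (camera adjusted p = 2.3e-05, and adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone 0 members were called, and 0 over all genes in limma, although 14 members had D-serine libraries above all vehicle libraries. The count over the list alone moved to 15 with weighted libraries and to 1, 9 and 2 without D-serine replicates 1, 2 and 3. Without D-serine replicate 1 the median was 0.21. Rrm2 and Rrm1, the subunits of ribonucleotide reductase, which makes the building blocks of DNA, were at 4.84 ± 0.220 and 2.38 ± 0.261 FPKM with vehicle and at 19.9 ± 13.7 and 5.20 ± 2.10 FPKM with D-serine (n = 3 each). The flap endonuclease gene Fen1 was at 2.72 and 4.67 FPKM and the chromatin assembly gene Chaf1b at 0.781 and 2.53 FPKM. Ccnd1, the G1 cyclin D1, was at 42.1 ± 3.19 and 43.1 ± 1.72 FPKM, a difference within the spread between replicates. Cdkn1a, the cell cycle inhibitor p21, was at 4.36 ± 0.771 and 5.73 ± 0.833 FPKM (limma adjusted p = 0.20).

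Over the 11737 genes tested one by one, limma called 9 at an adjusted p of 0.05, 1 higher and 8 lower. The called protein-coding genes were all lower with D-serine. Lipo1, a lipase-family gene on chromosome 19 (33775498 to 33787459, mm10), fell from 28.8 ± 2.11 to 8.88 ± 1.70 FPKM (log2 difference -1.61 ± 0.14 SE, adjusted p = 0.015, n = 3 each). Pzp, a secreted protease inhibitor (chromosome 6, 128483567 to 128526720), fell from 46.6 ± 4.17 to 15.4 ± 2.75 FPKM. Slc16a14, of the monocarboxylate transporter family (chromosome 1, 84905898 to 84935134), fell from 9.20 ± 0.534 to 3.36 ± 0.290 FPKM. Adra2b, an alpha-2 adrenergic receptor (chromosome 2, 127363208 to 127367221), fell from 58.7 ± 1.67 to 32.9 ± 2.15 FPKM, and Timp3, an inhibitor of matrix metalloproteinases (chromosome 10, 86300372 to 86349506), from 585 ± 6.38 to 347 ± 15.3 FPKM. Mtor was the other such gene. Of the 6 fits without 1 library, Lipo1, Pzp and Slc16a14 were called in 3 each, Adra2b in 2 and Timp3 and Mtor in 1 each, while the log2 difference stayed between -1.73 and -1.48 for Lipo1, -1.68 and -1.45 for Pzp, -1.27 and -1.18 for Slc16a14, -0.87 and -0.79 for Adra2b and -0.79 and -0.73 for Timp3. The remaining 3 calls, named after their values were seen, were small RNA genes, which a poly(A) library captures poorly: Mir6244 and Mir1957b were listed at 0 in all 3 D-serine libraries and Snora74a in all 3 vehicle libraries. No other gene rose at this threshold. The named genes nearest to a call among the higher ones were Vegfb, a vascular growth factor (52.3 ± 2.78 and 86.5 ± 3.59 FPKM), Adgrg3, an adhesion receptor (6.04 and 13.3 FPKM), Fam110a (3.91 and 9.26 FPKM), Cdkn3, a phosphatase of the cell cycle (2.27 ± 1.21 and 28.7 ± 17.3 FPKM), and Cox6b2, a cytochrome oxidase subunit (22.8 ± 7.02 and 81.6 ± 19.7 FPKM). Mrpl23 (76.5 and 136 FPKM), S100a13 (27.9 and 54.7 FPKM), Pbx4 (0.911 and 4.52 FPKM) and Ngfrap1 (21 and 36.5 FPKM) followed. Among the lower ones, Vwa1 (23.4 and 11.6 FPKM), Angptl7 (9.01 and 3.16 FPKM), Lrrc58 (25.5 and 12 FPKM) and Slc35a3 (46.7 and 21.2 FPKM) came next. The adjusted p of these 13 genes lay between 0.052 and 0.057. The log2 difference of Vegfb moved from 0.71 to 0.45 when a trend with transcript length and GC content was removed.

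The short list of calls sat beside a much wider difference. At an unadjusted p under 0.05 there were 3253 genes, 1536 higher and 1717 lower, where about 587 were expected by chance, and at an adjusted p under 0.1 limma gave 1315. The count of 9 moved to 332 when small RNA genes were left out, to 171 with a pseudocount of 0.1 and to 269 with weighted libraries. It moved to 437 without D-serine replicate 3, to 24 without D-serine replicate 1, and to 4, 3 and 2 without vehicle replicates 1, 2 and 3.

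Mtor, which encodes the kinase of both mTOR complexes, lies on chromosome 4 (148448611 to 148557683, mm10). Its libraries stood at 35.4, 30.1 and 33.3 FPKM with vehicle and at 18.5, 18.0 and 17.5 FPKM with D-serine, a log2 difference of -0.83 ± 0.094 (SE, limma adjusted p = 0.049). The call lay close to the threshold: without 1 library at a time the difference stayed between -0.89 and -0.78, and it passed in 1 of 6 such fits. Angptl7 (chromosome 4, 148495183 to 148500460), which was also lower without passing, runs antisense to Mtor inside its span, with 0 exon bases shared with Mtor exons in the annotation. Whether strand was used when reads were assigned is not given in the sources used here. Exosc10, which lies beside Mtor and is named for its position after its values were seen, was at 13.7 and 14.1 FPKM. Of the list of mTOR complex and pathway components, 21 of 28 tested members were lower, with a median log2 difference of -0.12 (camera adjusted p = 0.033, and adjusted p = 0.48 with an estimated correlation). Mtor was the 1 member that passed, both adjusted over the list alone and over all genes. Pdpk1, a kinase that activates AKT and S6 kinase, was at 5.88 and 3.93 FPKM, and Rraga, a GTPase of amino acid sensing, at 34.2 and 26.3 FPKM. Rps6kb1, which encodes S6 kinase, was at 7.14 ± 0.180 and 6.54 ± 0.285 FPKM (log2 difference -0.11), and Ddit4, an inhibitor of mTORC1, ranged from 14.2 to 100 FPKM with vehicle and from 6.50 to 59.7 FPKM with D-serine. The list's median was -0.19 without D-serine replicate 1, and its call ended without D-serine replicate 2 (median -0.089, adjusted p = 0.064), with a minimum of 5 FPKM (-0.11, adjusted p = 0.15) and with quantile normalization (-0.11, adjusted p = 0.082).

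**Figure D2:**
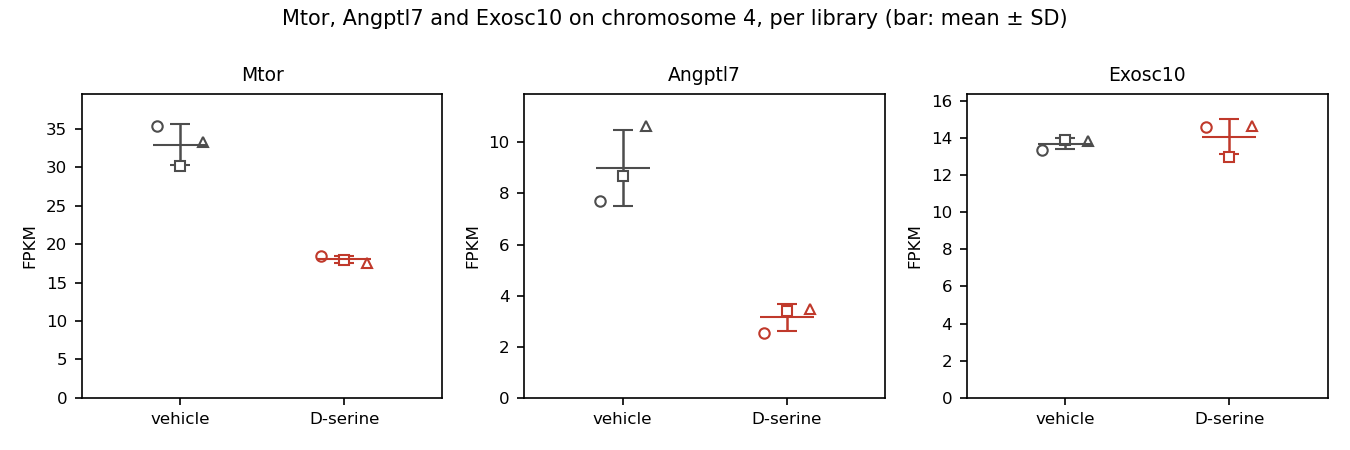
FPKM (vertical axes, each from 0) of Mtor, Angptl7 and Exosc10, which lie next to one another on chromosome 4, in the vehicle and D-serine libraries, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean and SD of 3 libraries. The D-serine libraries lie below the vehicle libraries for Mtor and Angptl7, and the groups overlap for Exosc10.

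The glycolysis list did not pass: 16 of 25 tested members were higher and 9 lower, with a median log2 difference of 0.057 (camera adjusted p = 0.17). The median was 0.037 without vehicle replicate 2, 0.090 and 0.091 without D-serine replicates 2 and 3, 0.11 with weighted libraries and 0.036 with the length and GC trend removed, and the list passed in none of these. Adjusted over the list alone 2 members rose, and over all genes 0 passed in limma. The 2 were Pgam2, the muscle form of phosphoglycerate mutase (169 ± 27.7 and 309 ± 72.1 FPKM), and Pfkfb1, an isoform of the enzyme that makes fructose 2,6-bisphosphate (0.531 ± 0.0939 and 1.54 ± 0.129 FPKM, n = 3 each). Gapdh was at 1471 ± 125 and 1841 ± 106 FPKM. The phosphofructokinase gene Pfkp (11.7 ± 1.87 and 13 ± 1.99 FPKM), the pyruvate kinase gene Pkm (140 ± 12.6 and 163 ± 29.2 FPKM) and the glucose transporter gene Slc2a1 (19.8 ± 1.49 and 24.5 ± 6.60 FPKM) had overlapping groups. Hk2, encoding a hexokinase, was near the floor, at 0, 0 and 0.0221 FPKM with vehicle and 0.0224, 0.0716 and 0.0226 FPKM with D-serine. Ldha was at 604, 689 and 599 FPKM with vehicle and at 570, 255 and 597 FPKM with D-serine, so that replicate 2 carried the group difference. Eno1 was at 182 ± 21.4 and 105 ± 42.5 FPKM, while its near-identical copy Eno1b was at 231 ± 18.6 and 295 ± 103 FPKM. Reads of the pair could be split either way between the copies, so both values are uncertain, and genes with many processed pseudogenes, such as Gapdh, Ldha and those of ribosomal proteins, share that limit.

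Transcripts that respond to amino acid supply through ATF4 and mTORC1 did not pass as a list, with 9 of 16 tested members higher and a median log2 difference of 0.13 (camera adjusted p = 0.44). The median turned to -0.16 with a minimum of 5 FPKM, where low members drop out (adjusted p = 0.81), and was 0.053 without D-serine replicate 2, 0.076 without vehicle replicate 3, 0.081 with no filter on low values, 0.078 with weighted libraries and 0.025 with the length and GC trend removed. The list had 0 members called, adjusted over the list alone or over all genes in limma. Mthfd2, of mitochondrial folate metabolism, was at 2.12 ± 0.554 and 4.97 ± 1.99 FPKM, and Atf5, a transcription factor of this response, at 7.56 and 11.6 FPKM. Vldlr was at 12.3 and 9.24 FPKM and Shmt2, mitochondrial serine hydroxymethyltransferase, at 231 ± 1.23 and 198 ± 11 FPKM. The serine, glycine and one-carbon list was lower, with 14 of 18 tested members down and a median log2 difference of -0.23 (camera adjusted p = 0.033, and adjusted p = 0.56 with an estimated correlation). Adjusted over the list alone 5 members fell and 1 rose, against 0 over all genes. Cbs, which joins serine to homocysteine, was at 82.5 ± 5.03 and 44.6 ± 8.04 FPKM, the glycine methylating enzyme Gnmt at 31.0 ± 2.25 and 14.2 ± 4.86 FPKM, and Agxt2 at 68.1 and 46.6 FPKM. This call ended without vehicle replicate 1 (adjusted p = 0.070), vehicle replicate 3 (0.074) or D-serine replicate 2 (0.087), and under quantile normalization (0.064). Dao, which encodes the D-serine degrading oxidase, was at 236 ± 9.42 and 196 ± 42.0 FPKM (limma adjusted p = 0.27), and Srr, encoding serine racemase, which converts L-serine to D-serine, at 46.3 ± 4.03 and 38.5 ± 5.60 FPKM (adjusted p = 0.22). Grin1, encoding the NMDA receptor subunit that binds D-serine, was listed at 0 in all 6 libraries. The list of D-amino acid handling genes did not pass (7 tested members, median -0.28, camera adjusted p = 0.17).

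Marker lists of nephron segments moved in both directions, and 8 of 12 tested lists passed camera in their own family, 5 higher and 3 lower; with an estimated correlation 0 passed (lowest adjusted p = 0.47). The list of androgen-responsive kidney genes had 8 of 8 tested members lower, a median log2 difference of -1.06 (camera adjusted p = 1.2e-04) and 7 members that fell adjusted over the list alone. Among them Cyp4b1, a cytochrome P450, was at 2690 ± 67.8 and 1162 ± 595 FPKM, the ornithine decarboxylase gene Odc1 at 1331 ± 428 and 650 ± 230 FPKM and the medium-chain acyl-CoA synthetase gene Acsm3 at 304 ± 86.5 and 91.0 ± 48.0 FPKM. Kap, by far the most abundant member, did not pass, with a log2 difference of -0.20 and overlapping groups (limma adjusted p = 0.41). Markers of the S3 segment of the proximal tubule were lower by a median of -0.76 (9 of 9 members, camera adjusted p = 3.7e-04), among them the transporter gene Slc7a13 at 438 ± 68.8 and 146 ± 56.2 FPKM, and those of S1 and S2 by -0.38 (13 of 13 members, adjusted p = 0.0048). The groups overlapped for S1 and S2: the mean log2(FPKM + 1) of members was 7.43, 6.82 and 7.305 with vehicle and 6.74, 6.52 and 7.24 with D-serine. Collecting duct principal cell markers were higher by a median of 0.62 (8 of 9 members, adjusted p = 6.6e-04), such as the water channel gene Aqp2 at 138 ± 25.6 and 239 ± 46.1 FPKM, and intercalated cell markers by 0.50 (11 of 11 members, adjusted p = 2.4e-04). The estimated correlation gave an adjusted p of 0.47 for each of these 5 lists. As fixed, the androgen-responsive and S3 lists share Slc7a12 and Cyp7b1. Adjusted over each list alone, 6 S3 and 4 S1 and S2 markers fell and 7 principal and 8 intercalated cell markers rose, against 0 over all genes in limma. Thick ascending limb markers did not pass (median -0.19, adjusted p = 0.21). Markers of fibroblasts, pericytes and smooth muscle were higher by 0.56 (adjusted p = 9.5e-04), endothelial markers by 0.38 (0.011) and distal convoluted and connecting tubule markers by 0.19 (0.015), with adjusted p from 0.47 to 0.48 for these 3 under an estimated correlation. The endothelial call ended without vehicle replicate 2 (median 0.20, adjusted p = 0.12) or D-serine replicate 3 (0.22, adjusted p = 0.090), and the distal tubule call without D-serine replicate 2 (0.13, adjusted p = 0.064). The distal tubule median was 0.32 without D-serine replicate 3 and 0.34 with the length and GC trend removed, and the fibroblast median 0.88 without D-serine replicate 1. Macrophage and dendritic cell markers (0.26, adjusted p = 0.21) and podocyte markers (0.42, adjusted p = 0.26) did not pass.

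**Figure D3:**
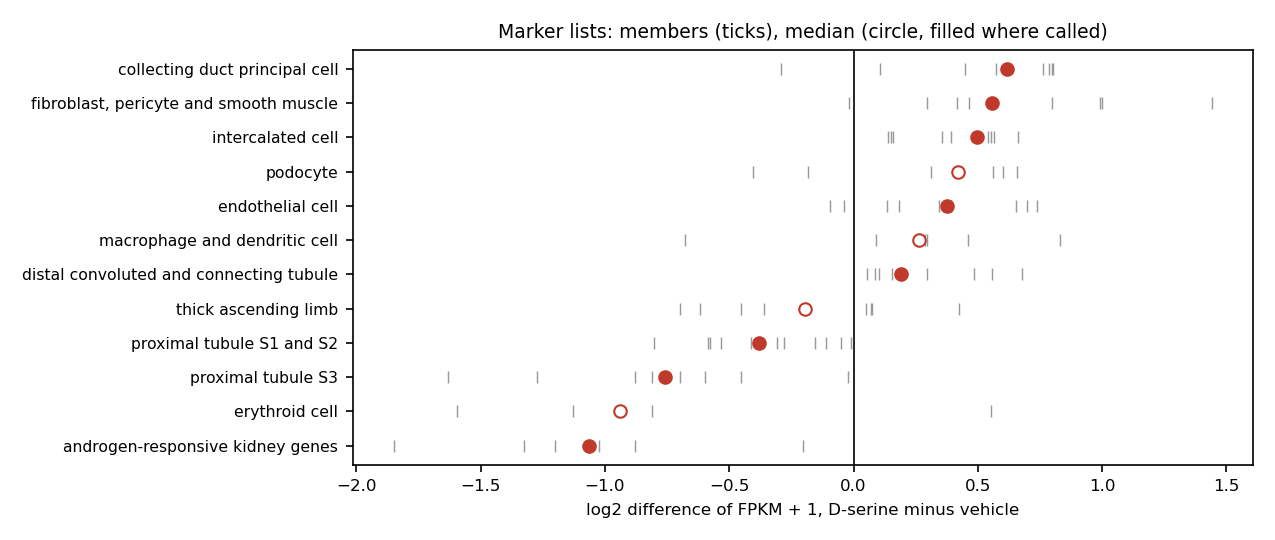
Log2 difference of FPKM + 1, D-serine minus vehicle (horizontal axis), for the tested members of 12 marker lists (ticks), with the median of each list as a circle that is filled where camera called the list with a preset correlation of 0.01. The medians run from -1.06 for androgen-responsive genes to 0.62 for principal cell markers of the collecting duct.

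Metabolic lists that passed were mostly lower on average with D-serine, as were proximal tubule markers, but not in each library. The mean log2(FPKM + 1) of fatty acid oxidation members was 6.42, 6.65 and 6.76 with vehicle. With D-serine it was 6.29, 6.11 and 6.82, so that D-serine replicate 3 was the highest library. As fixed, some of these lists share genes, so their falls are not wholly separate results. Slco1a1, Cyp4b1 and Cyp7b1 are in both the drug metabolism and the androgen-responsive list. Slc22a6, Slc22a7 and Cyp7b1 are in the drug metabolism list and in a proximal tubule list. Acsm3 is in the fatty acid oxidation and the androgen-responsive list. Drug metabolism and organic ion transport had 18 of 20 tested members lower (median -0.48, camera adjusted p = 3.8e-06, and adjusted p = 0.48 with an estimated correlation), with 13 that fell adjusted over the list alone and 0 over all genes. The organic anion transporter gene Slco1a1 was at 207 ± 45.5 and 88.8 ± 12 FPKM, Hsd11b1, which regenerates active glucocorticoid, at 133 ± 33.1 and 59.7 ± 5.85 FPKM, and Cyp2e1 at 2177 ± 151 and 1287 ± 297 FPKM. Fatty acid oxidation (22 of 30 lower, median -0.23, adjusted p = 0.017, and 0.58 with an estimated correlation) held its regulator Ppara at 19.8 and 11.5 FPKM and Fabp1, which was higher, at 1.06 and 3.41 FPKM. In fatty acid synthesis 10 of 14 were lower (median -0.41, adjusted p = 0.033, and 0.48 with an estimated correlation), with the desaturase gene Scd1 at 10.8 ± 2.36 and 4.75 ± 0.312 FPKM and Acly at 37.2 and 26.2 FPKM. The tricarboxylic acid cycle had 19 of 25 lower (median -0.21, adjusted p = 0.0034, and 0.56 with an estimated correlation), led by the cytosolic aconitase gene Aco1 at 150 ± 8.07 and 104 ± 9.80 FPKM. Adjusted over each list alone, 4 members fell and 1 rose in the first of these, 7 fell in the second and 1 in the third, against 0 over all genes. The oxidation call ended without vehicle replicate 3, D-serine replicate 1 or D-serine replicate 2 (adjusted p = 0.12, 0.13 and 0.068), and the synthesis call without vehicle replicate 3 or D-serine replicate 3 (0.073 and 0.084). The oxidation median was -0.11 without D-serine replicate 1 and -0.36 without D-serine replicate 3, the synthesis median -0.24 without D-serine replicate 3 and the tricarboxylic acid cycle median -0.12 without D-serine replicate 2.

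Ribosomal protein and respiratory chain genes were higher. Of cytosolic ribosomal protein genes 69 of 77 were higher (median 0.29, camera adjusted p = 3.7e-15, and adjusted p = 0.48 with an estimated correlation), with 44 that rose and 1 that fell adjusted over the list alone and 0 over all genes. Rps20 was at 766 ± 29.9 and 1122 ± 38.1 FPKM and Rps12 at 901 ± 63.9 and 1314 ± 56.9 FPKM. Of oxidative phosphorylation genes 55 of 71 were higher (median 0.24, adjusted p = 4.7e-06, and 0.56 with an estimated correlation), with 11 that rose and 1 that fell over the list alone and 0 over all genes. Atp5g1, of the ATP synthase, was at 704 ± 70.5 and 1075 ± 75.2 FPKM, and the complex I genes Ndufa11 and Ndufb7 at 50.5 and 80.1 FPKM and at 545 and 879 FPKM. Short transcripts were higher in the D-serine libraries in general: with the genes sorted by their longest transcript into 5 groups of equal size, the shortest group, up to 1826 nt, had a median log2 difference of 0.15 and the longest group -0.11. The shortest group held 59 of 77 ribosomal protein genes and 53 of 71 oxidative phosphorylation genes. With that trend removed the medians were 0.20 for ribosomal proteins and 0.087 for oxidative phosphorylation, and both lists passed. The correction used the longest annotated transcript, such as 3706 nt for Rps20 and 4715 nt for Atp5g1, and the expressed one was not determined. Where the expressed transcript is shorter, the removal may be incomplete, so these calls cannot separate the lists from the trend. The oxidative phosphorylation median was 0.14 without vehicle replicate 1 and 0.15 with quantile normalization.

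Chaperone genes were lower. Of endoplasmic reticulum chaperones and genes of the unfolded protein response 18 of 20 were lower (median -0.40, camera adjusted p = 3.2e-05, and adjusted p = 0.55 with an estimated correlation), with 7 that fell over the list alone. Without D-serine replicate 2 the median was -0.26. Hspa5, the main chaperone BiP, was at 280 ± 31.0 and 169 ± 37.3 FPKM and Herpud1 at 231 ± 28.2 and 141 ± 9.13 FPKM. Of the heat shock list 15 of 17 were lower (median -0.33, adjusted p = 7.9e-04, and 0.48 with an estimated correlation), with 9 that fell and 2 that rose over the list alone. Hsph1 was at 70.0 ± 9.41 and 34.1 ± 9.28 FPKM and Hsp90ab1 at 698 ± 54.2 and 431 ± 71.4 FPKM, while the small chaperone gene Cryab was at 31.2 ± 1.84 and 54.7 ± 10.2 FPKM. Over all genes 0 members of either list passed.

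Lists of injury, matrix, interferon and early response genes were higher. Kidney injury and repair had 15 of 18 members higher (median 0.41, camera adjusted p = 0.0035, and adjusted p = 0.48 with an estimated correlation), with 5 that rose over the list alone: Lcn2, the tubular injury marker NGAL (2.12 ± 1.46 and 7.15 ± 1.97 FPKM), Spp1 or osteopontin (350 ± 31.5 and 529 ± 80.7 FPKM) and the keratin genes Krt7, Krt18 and Krt19, which collecting duct cells also express. Krt7 was at 97.7 ± 12.8 and 163 ± 29.6 FPKM. Extracellular matrix genes (17 of 18 higher, median 0.30, adjusted p = 0.0014, and 0.55 with an estimated correlation) had 2 that rose over the list alone, Tagln (8.75 ± 1.57 and 18.5 ± 3.94 FPKM) and Acta2 (8.54 ± 0.984 and 18.6 ± 5.51 FPKM), which are genes of smooth muscle and not of the matrix. As fixed, the matrix list shares both of them, Col1a1 and Col3a1 with the fibroblast, pericyte and smooth muscle markers. The rises of these lists are therefore not wholly separate results. Interferon response genes (13 of 15 higher, median 0.31, adjusted p = 0.0041, and 0.48 with an estimated correlation) had 4 that rose over the list alone, among them Bst2 at 8.0 and 13.2 FPKM and Cxcl10 at 0.910 and 1.87 FPKM. Immediate early genes (16 of 20 higher, median 0.30, adjusted p = 0.033, and 0.58 with an estimated correlation) had 0 over the list alone. Fos was at 4.09 ± 1.19 and 8.46 ± 3.51 FPKM and Ier2 at 8.42 and 19.9 FPKM. That list's median was 0.047 without D-serine replicate 2 (adjusted p = 0.37) and 0.15 without vehicle replicate 1 (adjusted p = 0.29), and its call also ended with quantile normalization (adjusted p = 0.060), weighted libraries (0.12) and the length and GC trend removed (0.090). The injury median was 0.66 without D-serine replicate 3 and 0.23 with no filter on low values. The matrix median was 0.48 and 0.20 without D-serine replicates 1 and 2, and 0.19 with a minimum of 5 FPKM or with no filter. The interferon median was 0.13 with no filter. No member of these 4 lists passed over all genes in limma.

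**Figure D4:**
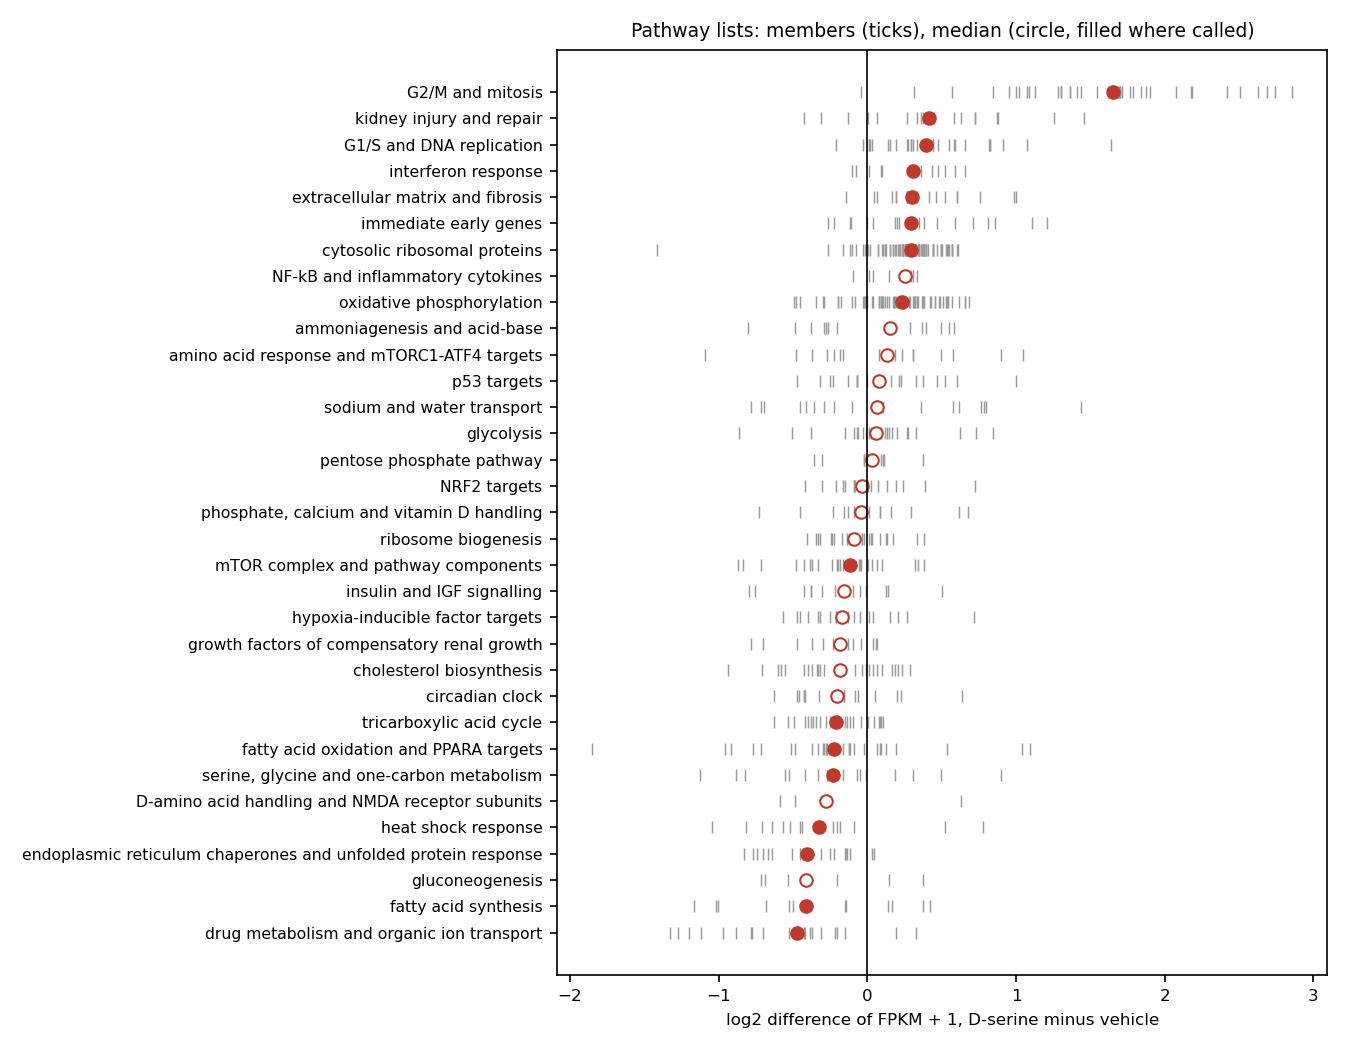
Log2 difference of FPKM + 1, D-serine minus vehicle (horizontal axis), for the tested members of 33 pathway lists (ticks), with the median of each list as a circle that is filled where camera called the list with a preset correlation of 0.01. The G2/M and mitosis list has the highest median, 1.65, and drug metabolism and organic ion transport the lowest, -0.48.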

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

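The length and GC correction, the values of marker lists under other settings, and the counts over a list alone under other settings were chosen after seeing the data. The count of called genes depended on the processing, and the cause was not tested. From 9 genes (1 higher, 8 lower) it moved to 171 (78, 93) with a pseudocount of 0.1, to 221 (110, 111) with 0.01, to 132 (45, 87) with a minimum of 5 FPKM, to 269 (123, 146) with weighted libraries and to 332 (148, 184) without small RNA genes. It was 6 with 5 lower both for limma without the trend and for FPKM rescaled to a fixed sum. Leaving out 1 library gave 2 to 437 genes, 0 to 213 higher and 2 to 224 lower, with 2 without vehicle replicate 3 and 437 without D-serine replicate 3. Same-numbered samples did not deviate together (correlations of deviations -0.070, 0.0031 and 0.067). No pairing by number was seen, but 3 libraries per group are too few to exclude one. With the replicate block 2 genes were called, 0 higher and 2 lower.

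Camera called 16 lists, and 13 to 18 without 1 library. With an estimated correlation 0 lists were called and with fry 1, the ribosomal proteins. G2/M and mitosis (median 1.65) was not called with an estimated correlation (adjusted p = 0.48) or fry (0.077), nor was G1/S and DNA replication (0.39; 0.55 and 0.19) or the mTOR components (-0.12; 0.48 and 0.059), whose call also ended with a minimum of 5 FPKM (-0.11, adjusted p = 0.15) and quantile normalization (-0.11, adjusted p = 0.082). The ATF4 target list reversed to -0.16 with a minimum of 5 FPKM (adjusted p = 0.81), where its low members drop out. Without 1 library the medians ran from 1.17 to 1.89 for G2/M, 0.21 to 0.45 for G1/S, -0.19 to -0.089 for the mTOR components, 0.053 to 0.13 for ATF4 targets and 0.037 to 0.091 for glycolysis, which was not called under any alternative. Over the list alone, 31 to 36 G2/M members rose without 1 library, and 12 with a minimum of 5 FPKM, which tests fewer of them. For G1/S the count over the list alone was 0, and 0 to 9 without 1 library.

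Of 1782 values of 100 named genes under the alternatives, 1518 kept their direction and side of the threshold, 39 lost the call, 223 gained it and 2 reversed: Rps6kb1 (0.035 with the length and GC correction) and Ccnd1 (-0.0086 without vehicle replicate 2, and up to 0.093 without vehicle replicate 1). Mtor kept its call under 8 of 18 alternatives (adjusted p from 0.030 to 0.23). Depth limits low genes most, with about 15.7 fragments behind 1 FPKM of a 2 kb transcript.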

Other observations

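Ren1, the gene of renin, stood out among the vascular markers, at 34.5 ± 15.3 FPKM with vehicle and 90.05 ± 10.4 FPKM with D-serine (SD, n = 3 each; limma adjusted p = 0.063 over all genes, 0.0051 adjusted over the list alone). Among growth factor genes, whose list did not pass (median -0.18, camera adjusted p = 0.063), Met, the receptor of hepatocyte growth factor, was at 28.8 and 16.5 FPKM and Egf at 267 and 167 FPKM, and both fell when adjusted over the list alone. The transporter gene Slc5a8 fell from 113 to 75.7 FPKM and the amino acid transporter gene Slc1a5 rose from 20.7 to 33.0 FPKM, again over their list alone. The vacuolar ATPase gene Atp6v0c, named after its values were seen, was at 236 and 94.5 FPKM (limma adjusted p = 0.057).

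Pathway lists that did not pass camera had medians between -0.41 for gluconeogenesis and 0.26 for NF-kB and inflammatory cytokines. Cholesterol biosynthesis (-0.19), the circadian clock (-0.20), insulin and IGF signalling (-0.15), hypoxia-inducible factor targets (-0.17), ribosome biogenesis (-0.091), phosphate, calcium and vitamin D handling (-0.042) and NRF2 targets (-0.037) were on the lower side. The pentose phosphate pathway (0.032), p53 targets (0.080), sodium and water transport (0.064) and ammoniagenesis (0.15) were on the higher side. Of the marker lists, erythroid genes had a median of -0.94 over 5 members (camera adjusted p = 0.84). The lists for thin limb, neutrophils and adipocytes had 3 tested members each, sex-linked genes 4, those for B cells, skeletal muscle and pancreas 1, and those for T cells, adrenal gland and urothelium 0, so none was tested. Xist lay at 0.0214 FPKM or lower in all 6 libraries and Ddx3y between 6.05 and 9.29 FPKM.

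Each test below was chosen after the result it bears on was seen. Splitting the 6 libraries into other groups of 3 gives 10 splits, too few for a share under 0.05. The real split called 9 genes and the highest other split 4, and the real one called 16 pathway lists and the highest other split 14. For the median size of a list, the real and the highest other value were 1.65 and 0.96 for G2/M and mitosis, 0.39 and 0.28 for G1/S, 0.12 and 0.084 for mTOR components, and 0.13 and 0.12 for ATF4 targets, and in each of these 6 results 1 of the 10 splits, the real one, was as large. For glycolysis 5 of the 10 splits were as large, with 0.057 for the real split and 0.13 for the highest other. All list counts here are by camera with the preset correlation.

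The G2/M and mitosis genes were higher with D-serine. The trend toward short, GC-rich transcripts in the D-serine libraries argues against itself as the cause, because the median was 1.70 with the trend removed. A single D-serine library does not account for it either, since the lowest median without any 1 of the 3 was 1.17. Dividing immune cells may contribute and cannot be told apart from dividing kidney cells: the macrophage and dendritic cell markers had a median of 0.26 and did not pass, but resident cells set a baseline that could hide a small dividing share. D-serine itself remains the open biological explanation, and a difference between the mice other than D-serine was not tested.

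Mtor was lower with D-serine, as was Angptl7 inside its span. With the length and GC trend removed the difference was -0.83 ± 0.086 (SE), so that trend is not the cause. Whether reads of Angptl7 were counted for Mtor was not tested and cannot be told from FPKM. Of 28 tested genes within 1 Mb, 4 (14.3%) were lower at an unadjusted p under 0.05, against 14.7% of the other genes (Fisher's exact p = 1, odds ratio 0.97 with a 95% interval of 0.24 to 2.82), which shows no excess. An equal fall across the region is excluded, since 25 of the 28 lay above the log2 difference of Mtor by more than 2 SE of the difference. A change confined to a shorter stretch, such as a sequence variant carried by 1 group of mice, may also explain it and was not tested.

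Androgen-responsive and S3 genes were lower, and collecting duct and intercalated genes higher. The length and GC trend does not account for either part, with medians of -1.09 for androgen-responsive genes and 0.54 for principal cells once it was removed. A lower share of proximal tubule in the tissue would raise the other segments alike. Collecting duct and thick ascending limb scores moved apart by 0.70 (log2, SD between libraries 0.14), the latter changing by -0.19. But distal tubule and intercalated cell scores rose by 0.29 and 0.41, near the 0.51 of principal cells, and the thin limb score, over 3 members, by 0.044. The gap depends on the segment chosen, so a lower share cannot be told apart for the collecting duct rise. Nor can it be for the fall: androgen-responsive genes fell further than S1 and S2 markers, by -0.72, but the SD between libraries was 0.37. Kap, an androgen-regulated gene of the list, had a log2 difference of only -0.20 with overlapping groups. Lower androgen signalling, or a response of the S3 segment to D-serine, may be involved and was not tested.

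The small RNA genes gave 3 of the 9 calls. Of 99 tested, 12 were above 0 in exactly 3 libraries, and 3 of these in the 3 libraries of 1 group. D-serine replicate 2 stood apart from the other libraries on the second principal component (22.2% of the variance) and had the lowest library weight, 0.394.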
